A study of Bos taurus with 15 samples.

How the data were processed

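RNA was measured in 15 libraries of bovine meniscal fibrochondrocytes at day 28, 3 in each of 5 groups, with groups and replicate numbers taken from the sample labels. Per the labels' protocols, tissues were cut into regions, each region was dissected further, RNA was extracted with a Direct-zol kit, and libraries were made by oligo-dT priming with a sample barcode and a molecular identifier followed by tagmentation. A library of this kind reads mainly the 3' ends of transcripts, so that values are not divided by gene length. Per the submitters' processing notes, STAR 2.7, SAMtools 1.21, featureCounts from Subread 2.1.1 and MultiQC 1.33 were used. The genome build, the annotation, the settings of the counting step and whether counts were collapsed by molecular identifier are not given in the sources used here. If they were not, PCR copies count as separate reads, and intervals from counts would be too narrow.

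The deposited table has 38093 rows, 38001 bovine Ensembl genes and 92 ERCC spike-in sequences, and 2 columns per library. The first kind holds CPM that the authors deposited, and recomputing it as the count divided by the library's column total, times 1e+06, gave the same values (largest difference 0). The second kind holds expected counts that the authors deposited: 13.5% to 16.3% of the nonzero values of a library are not whole (tolerance 1e-06), and 41.5% to 47.4% of a library's counts sit in such values, as when a read that fits several genes is shared among them. Values of genes with near-identical copies are therefore uncertain, and the share of a gene's counts in such values is given for some genes below. Other named genes also carry such shares, among them TAGLN (53.2%), CCN2 (47.7%) and COL3A1 (46.3%). Every value column matched 1 sample. Gene symbols were taken from the table, where 17715 gene rows carry no symbol and 2007 carry a symbol that several identifiers share. No coordinates, gene lengths or GC contents were used, since no annotation of the build was given.

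Library totals ran from 2060781 to 7415701 counts. Spike-in rows were left out of library sizes and tests, and the expected counts were rounded to whole numbers before testing. Genes were kept by filterByExpr of edgeR with its default limits (a count of 10 scaled to library size and a total of 15), which left 11834 genes, and libraries were scaled by TMM (factors 0.934 to 1.049). One quasi-likelihood model with a mean per group was fitted to all 15 libraries with edgeR 4.0.16 in R 4.3.3, so that the groups share one estimate of the spread, and each comparison was a two-sided contrast of it, adjusted over genes by the method of Benjamini and Hochberg with a threshold of 0.05. Values per group are TMM-normalised CPM, mean ± SD of 3 libraries, and log2 fold changes carry the standard error of the model. AFP and the other liver and lung transcripts are given as CPM of the library total.

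There were 10 comparisons fixed before the data were examined: anchored against unanchored in each region, post against middle in each mold type, the interaction of anchoring and region, each molded group against no mold and the mean of the 4 molded groups against no mold. After the data were seen, 2 more were added: anchored against unanchored averaged over regions and post against middle averaged over mold types.

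Gene lists, 33 with 578 distinct genes, were also written before the data were examined, and 29 had at least 4 tested members. They were tested with camera of limma 3.58.1 on voom values with a correlation between genes preset at 0.01, adjusted over the lists within a comparison. The correlation was also estimated from the data, and no list call held with it. In addition, fry asked whether the genes of a list moved on balance one way. It passed 7 of the 8 lists that camera called for molded against no mold, 2 of 11 for anchored and 2 of 8 for unanchored post against middle, 0 of 4 and 0 of 2 for anchored against unanchored middle and post, and 0 of 1 for the interaction. Beside most lists the number of members past the threshold over all genes is given with the number adjusted over the list alone. Some lists, among them those summarised together, do not carry both numbers.

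The genes named were set by a rule fixed before the data were examined: per comparison up to 8 of the largest rises and 8 of the largest falls among genes past the threshold with a symbol, a mean of at least 10 CPM in a group compared and no overlap of values between the libraries of the sides compared; up to 3 members of each list past camera's threshold; and a panel of 20 genes, of which the text gives part in each comparison, whether or not they passed. Of the panel, COL10A1, TNMD and MMP13 had too few counts to be tested. Genes outside the rule that stand in the text were chosen after their values were seen: the markers of other cell types, tested or not, AFP, SFTPC and those of the closing observations. One result withheld for evaluation is not reported here.

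The edgeR step was tested on simulated counts with the means and library sizes of the real data and 200 genes changed by 1.5, 2 or 4 fold. A further small list of genes was raised 1.5 fold in the same counts and is not part of the recovered shares. In the mean of the molded groups against no mold (11702 genes) the step recovered 55.4%, 82.1% and 95.5% of the 200 genes by fold. All of these had the right sign, and 8 of 172 calls, which can include the raised list, were false. In anchored post against anchored middle (11704 genes) it recovered 41.8%, 83.1% and 93.9%, and in unanchored post against unanchored middle (11710 genes) 55.2%, 85.1% and 96.9%. Overlaps between comparisons against no mold were set beside 20 simulations of unchanged groups, in which libraries vary independently gene by gene.

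Alternatives were RLE and upper-quartile scaling, no filter (21304 genes) and a stricter filter of 5 CPM in 3 libraries (9836 genes), DESeq2 1.42.0, limma voom with quality weights, a model of only the groups compared, the replicate number as a block, a test against a 2-fold change, a rank-based form of camera and leaving out each library in turn. Those added after the data were seen were thinning every library to the smallest total, keeping only the 6455 tested genes whose values are all whole, and leaving out the 3 shallowest libraries (at most 2986944 counts). Regroupings of the libraries numbered at most 100 per comparison. Intervals of slopes and ratios came from 1000 bootstrap resamples of genes, which are not independent. Relations across libraries were tested with 100000 permutations in Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9.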

Results

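Polyadenylated RNA was profiled in bovine meniscal fibrochondrocytes, the matrix-producing cells of the knee meniscus, after 28 days of culture in collagen. The cells spent 3 days in a growth medium with 10% fetal bovine serum and then 25 days in a chondrogenic medium that contained ascorbic acid (50 µg/ml), dexamethasone and 10 ng/ml of the growth factor TGF-β3. Tissues were cast in 3D-printed molds, either with or without post anchors, and were divided into a middle and a post region, which gave 4 molded groups: unanchored middle, unanchored post, anchored middle and anchored post. Cells in collagen that was not cast in a mold formed the fifth group. Each group held 3 libraries, 15 in all.

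Total counts per library ranged from 2060781 to 7415701. The no-mold libraries were the shallowest as a group, with 2060781, 4466562 and 2128257 counts in libraries 1, 2 and 3, and the molded libraries lay between 4970209 and 7415701 except anchored middle library 2, with 2986944. Libraries of one group correlated at r = 0.970 to 0.991 and those of different groups at r = 0.958 to 0.992 across genes, which are not independent replicates. Every same-group pair differed by more than counting noise (chi-square per degree of freedom 2.91 to 13.7). The closest pair lay across groups, unanchored middle library 2 and anchored middle library 3, at 1.89 (r = 0.992). No library was taken for a second deposit of another. Separate preparations of one RNA would differ as well. The labels do not say whether the replicates of a group came from separate tissues, so the p-values below measure only the spread between these libraries, which may be technical.

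The first principal component, 27.0% of the variance, separated the no-mold libraries from the molded ones. No-mold libraries 1 and 3 scored 38.8 on it, no-mold library 2 scored 17.8, and no molded library scored above 2.94. The second component, 15.5% of the variance, set anchored middle library 2 apart with a score of 37.8, against at most 11.1 for the other libraries. Mitochondrial messenger RNA made up 1.52% ± 0.188 of counts in the no-mold group (SD, n = 3), 2.21% ± 0.145 in unanchored middle, 1.81% ± 0.249 in unanchored post, 2.06% ± 0.295 in anchored middle and 1.76% ± 0.124 in anchored post.

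**Figure D1:**
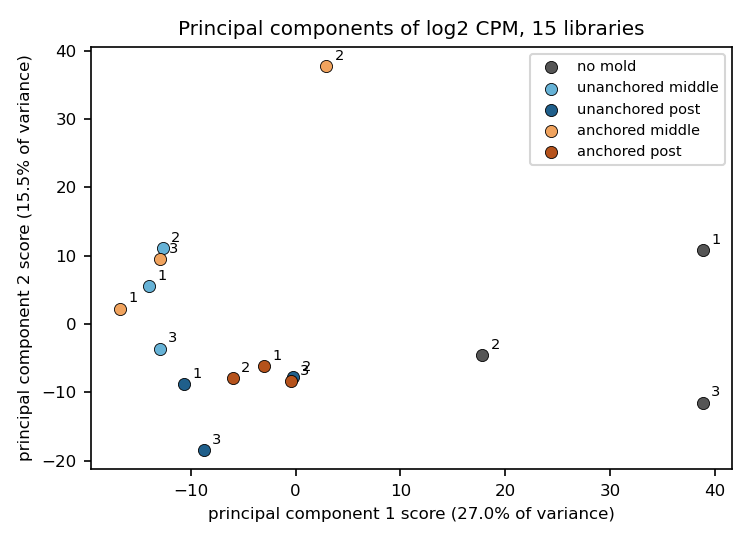
Scores of the 15 libraries on the first (27.0% of variance) and second (15.5%) principal components of log2 CPM, coloured by group and numbered by replicate. The no-mold libraries lie to the right, between 17.8 and 38.8 on the first component, and anchored middle library 2 lies alone at 37.8 on the second.

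Among markers of other cell types, 1 of 13 endothelial, 1 of 10 Schwann and neural, 1 of 14 skeletal muscle, 2 of 8 red blood cell and 4 of 16 leukocyte and macrophage genes had enough counts to be tested. Of the others, over all 15 libraries together, the endothelial gene PECAM1 had 10 counts. The leukocyte genes PTPRC, CSF1R and CD68 had 25, 55 and 64.5, the Schwann cell gene SOX10 had 1 and the muscle gene CKM 5. The tested members were ERG (endothelial, 70.3 to 75.8 CPM as group means), S100B (Schwann and neural, 353.5 to 437 CPM), ACTA1 (muscle, 1.72 to 5.28 CPM) and the hemoglobin genes HBB and HBM. HBM was lower in the mean of the molded groups, with 3.42 CPM without a mold and at most 0.976 in a molded group (log2 fold change -3.12, edgeR adjusted p = 0.000827). The hypertrophic cartilage collagen COL10A1 had 9 counts in total, the tendon gene TNMD 2 and the collagenase MMP13 1, also below the limit for testing. Of 6 measured markers of mural cells and 4 of macrophages and other immune cells, 0 changed by edgeR in any of the 6 comparisons for which gene lists were tested (camera adjusted p at least 0.319 for mural and 0.524 for macrophage markers in these comparisons).

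The comparison of molded with unmolded tissue asked how shaping the collagen changed the cells. Casting in a mold went with lower expression of cartilage genes. COL2A1 (ENSBTAG00000013155), the main collagen of hyaline cartilage, averaged 708 ± 181 CPM without a mold and 65.5 ± 30.6 in unanchored middle, 48.4 ± 25.2 in unanchored post, 155.5 ± 105 in anchored middle and 66.6 ± 11.7 in anchored post (SD, n = 3 each). Its log2 fold change, mean of the 4 molded groups against no mold, was -3.24 (SE 0.248, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 1.59e-08). COL9A2, a collagen that coats type II fibrils, fell by 2.38 on the log2 scale (SE 0.285, edgeR adjusted p = 5.97e-06), and SOX9, the transcription factor that drives chondrocyte genes, fell by 0.79 (SE 0.078, edgeR adjusted p = 5.86e-07). Of 14 measured cartilage matrix genes, 10 fell and 0 rose, or 11 and 0 adjusted over the list alone (camera adjusted p = 5.14e-11, but adjusted p = 0.153 with an estimated correlation). ACAN, COMP and PRG4, the genes of aggrecan, cartilage oligomeric matrix protein and lubricin, were also lower in the mean of the 4 molded groups, by 0.85, 0.76 and 0.60 on the log2 scale (edgeR adjusted p = 0.00601, 0.0189 and 0.0046), though COMP and PRG4 were not lower in anchored middle. ACAN averaged 212.7 CPM without a mold, 148.1 and 192 in unanchored and anchored middle and 79.7 and 87.3 at the posts. COMP averaged 1795 CPM without a mold, 1392 and 2189 in unanchored and anchored middle and 581 and 720 at the posts. PRG4 averaged 275.6 CPM without a mold, 260.5 and 279.6 in the middle groups and 129.2 and 113.8 at the posts. These 3 calls ended without no-mold library 1 (adjusted p = 0.089, 0.352 and 0.0701), and 80.6% of PRG4 counts sat in values that include split reads.

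Some fibrous matrix genes moved the other way. Of 11 measured small leucine-rich proteoglycans, which bind and space collagen fibrils, 4 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.00514, 0.153 as adjusted p with an estimated correlation and 0.179 with rank-based camera). Among them OGN (osteoglycin) went from 30.0 ± 1.7 CPM without a mold to between 76.5 ± 8.55 and 111.5 ± 9.63 in the molded groups (SD, n = 3), a log2 fold change of 1.54 (SE 0.138, edgeR adjusted p = 1.58e-07). Of 12 tendon and fibrous tissue genes, 5 rose and 1 fell, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.00119, adjusted p = 0.23 with an estimated correlation). TNC, the gene of the matrix glycoprotein tenascin C, rose by 1.00 on the log2 scale (SE 0.138, edgeR adjusted p = 2.92e-05), and ELN, the gene of elastin, was the member that fell, by 0.85 (edgeR adjusted p = 0.00366), a call that ended without no-mold library 1 (adjusted p = 0.0855). ELN averaged 1776 CPM without a mold, 1171 and 1624 in unanchored and anchored middle and 654 and 762 at the posts, so anchored middle lay close to no mold. The gene of the most abundant fibrous collagen did not pass: COL1A1 had 11050 ± 2630 CPM without a mold and a log2 fold change of -0.04 (SE 0.161, edgeR adjusted p = 0.916), with 61.4% of its counts in values that include split reads. SCX and MKX, transcription factors of tendon, had log2 fold changes of 0.21 and 0.20 and did not pass either (edgeR adjusted p = 0.482 and 0.253).

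Of the contractile genes fixed for display, ACTA2, the gene of smooth muscle actin, had a log2 fold change of 0.36 (SE 0.113, edgeR adjusted p = 0.0308), a call that ended without no-mold library 1 (adjusted p = 0.183) or 3 (0.139). Of its counts, 85.9% sat in values that include split reads. CNN1, the gene of calponin, fell by 0.50 on the log2 scale (SE 0.162, edgeR adjusted p = 0.0379), a call that ended when any 1 of the 3 no-mold libraries (adjusted p = 0.166, 0.0733 and 0.135) or any 1 of 4 molded libraries (0.0512 to 0.0553) was left out. The fall was not common to the molded groups: CNN1 averaged 37.9 CPM without a mold and 36.0 in anchored post. It averaged 20.5 in unanchored middle, 24.2 in unanchored post and 29.25 in anchored middle. TAGLN (transgelin) at 0.17 and the proliferation marker MKI67 at -0.50 did not pass (edgeR adjusted p = 0.285 and 0.267).

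The hypoxia, immediate early and inflammation lists were lower in the molded groups by camera with its preset correlation, and none of them with an estimated correlation. Of 20 hypoxia-responsive genes, 11 fell and 0 rose, or 14 and 0 adjusted over the list alone (camera adjusted p = 5.76e-07, adjusted p = 0.334 with an estimated correlation). ADM, which encodes the vasodilator peptide adrenomedullin, fell by 1.07 on the log2 scale (SE 0.175, edgeR adjusted p = 0.000229). VEGFA, the angiogenic growth factor, had a log2 fold change of -0.58 (edgeR adjusted p = 0.0401), a call that ended when any of 6 single libraries was left out: no-mold library 1 (adjusted p = 0.221) or 3 (0.137), unanchored middle library 1 (0.0563) or 2 (0.0541), unanchored post library 1 (0.0554) or anchored middle library 3 (0.0521). Of 16 immediate early genes, 7 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 1.1e-04, adjusted p = 0.153 with an estimated correlation), among them FOSL1, a subunit of the AP-1 transcription factor, by 0.87 on the log2 scale (SE 0.121, edgeR adjusted p = 2.92e-05). Of 14 inflammation genes, 4 fell and 1 rose, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0208, adjusted p = 0.23 with an estimated correlation). The member that rose was VCAM1, an adhesion molecule for leukocytes, by 2.48 (SE 0.534, edgeR adjusted p = 0.00256) from 0.963 ± 0.838 CPM.

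Of 14 glucocorticoid-responsive genes, 6 fell and 1 rose, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.00119, adjusted p = 0.153 with an estimated correlation). The members with the largest falls were metallothioneins, proteins that bind zinc and copper and whose genes also respond to metals: MT1E fell by 1.26, MT2A by 1.08 and MT1A by 1.03 on the log2 scale (edgeR adjusted p = 4.2e-05, 5.86e-07 and 5.86e-07). These genes resemble one another, and 100%, 94.5% and 69.8% of their counts sat in values that include split reads, so which of them changed is uncertain. Of 13 mitochondrially encoded genes, 2 rose and 0 fell, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.0317, adjusted p = 0.723 with an estimated correlation). That list call ended without no-mold library 1 (adjusted p = 0.145) or 3 (0.109), unanchored middle library 3 (0.0505) or anchored post library 2 (0.0582).

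Beyond the lists, the largest rises in molded tissue included genes of secreted factors. FGF7, a growth factor for epithelial cells, went from 7.73 ± 1.23 CPM to between 21.7 ± 5.88 and 28.3 ± 0.465 (SD, n = 3), a log2 fold change of 1.62 (SE 0.181, edgeR adjusted p = 2.42e-06). ANGPT1, a ligand that stabilises vessels, rose by 1.80 (SE 0.242, edgeR adjusted p = 2.25e-05), and CHRDL1, a BMP antagonist, by 1.56 (SE 0.181, edgeR adjusted p = 4.12e-06). AOX1 (aldehyde oxidase), CCDC3, SYTL2 and CCDC112 rose by 1.97, 1.67, 1.56 and 1.54 on the log2 scale. Among the largest falls were S100A1 and S100A2, calcium-binding proteins, by 2.28 (SE 0.198) and 1.20 (SE 0.16), with edgeR adjusted p = 1.12e-07 and 2.04e-05. UPP1 (uridine phosphorylase), IGFBP5 (an insulin-like growth factor binding protein) and TET2 (a DNA demethylase) fell by 1.75, 1.64 and 1.24.

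In total, 1888 of 11834 genes passed at an adjusted p of 0.05, 952 higher and 936 lower with a mold (edgeR). The count was 1127 without no-mold library 1 and 856 without no-mold library 3. It was 335 without the 3 shallowest libraries (no-mold 1 and 3, anchored middle 2), which leaves 1 no-mold library that is assumed to vary like the other groups. The no-mold libraries also differed from the molded ones in depth, in their mitochondrial share (above) and in AFP, the gene of a fetal serum protein made by the liver, which stood at 91.3 ± 42.4 CPM without a mold and at 32.8 ± 8.42 to 61.8 ± 18.4 in the molded groups (SD, n = 3).

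**Figure D2:**
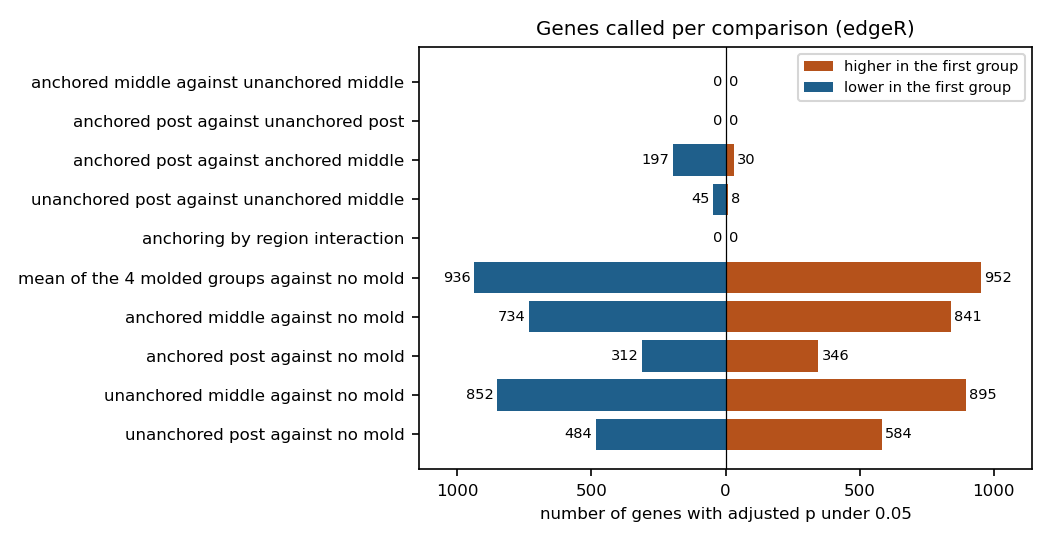
Number of genes with an edgeR adjusted p under 0.05 in each of the 10 planned comparisons, higher in the first-named group to the right and lower to the left. The mean of the molded groups against no mold has 952 and 936 genes, post against middle has 30 and 197 in anchored and 8 and 45 in unanchored tissues, and both comparisons of anchored with unanchored tissue and the interaction have 0.

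Taken one group at a time, anchored middle differed from no mold in 1575 genes, unanchored middle in 1747, anchored post in 658 and unanchored post in 1068 (edgeR). These counts depended on single libraries. For anchored middle, 768 genes passed without no-mold library 3 and 1015 without anchored middle library 3. For unanchored middle, 1162 and 790 passed without no-mold library 1 or 3, and 1144 and 1147 without unanchored middle library 1 or 2. For anchored post, 280 and 251 passed without no-mold library 1 or 3, and 373 and 436 without anchored post library 1 or 2. For unanchored post, 605 and 496 passed without no-mold library 1 or 3, and 527 and 576 without unanchored post library 1 or 3. Without the 3 shallowest libraries, the counts were 411, 421, 82 and 170 in the order of the first sentence.

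The same no-mold libraries enter all 4 of these comparisons. Anchored and unanchored middle shared 637 higher and 551 lower genes, against 63.6 and 52.8 for independent lists, and their log2 fold changes correlated at r = 0.88 across genes. Anchored and unanchored post shared 293 higher and 243 lower genes, against 17.1 and 12.8 for independent lists (r = 0.86). Across the 6 pairs of comparisons r was 0.74 to 0.88 and the covariance 0.128 to 0.176. In 20 simulations of unchanged groups against the same no-mold libraries, r was 0.64 to 0.66, the covariance 0.0414 to 0.0417, and at most 0.1 genes were shared on average. The 3 no-mold libraries cannot be divided into 2 sets of at least 2, so the overlap was not repeated with separate controls, and part of the excess may come from the shared controls.

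The comparison of post with middle regions asked how the parts of a tissue differed. In anchored tissues, several matrix genes were lower at the post. COMP (ENSBTAG00000004630) averaged 2189 ± 912 CPM in anchored middle and 720 ± 83.6 in anchored post (SD, n = 3), a log2 fold change of -1.60 (SE 0.293, edgeR adjusted p = 0.0036). PRG4, the gene of the lubricant of joint surfaces, averaged 279.6 ± 79.7 and 113.8 ± 22.9 CPM (SD, n = 3), a log2 fold change of -1.29 (SE 0.182, edgeR adjusted p = 0.000455). Of 14 cartilage matrix genes, 6 fell and 0 rose, or 9 and 0 adjusted over the list alone (camera adjusted p = 8.48e-10, adjusted p = 0.258 with an estimated correlation). CHAD (chondroadherin) fell by 1.23 on the log2 scale (edgeR adjusted p = 0.00711), a call at 0.0507 without anchored post library 3. ACAN fell by 1.12 (edgeR adjusted p = 0.0267), a call that ended without anchored middle library 2 (adjusted p = 0.0833) or 3 (0.0667) and without anchored post library 1 (0.0577), 2 (0.112) or 3 (0.0702). COL2A1 had a log2 fold change of -1.18 (SE 0.378) and did not pass (edgeR adjusted p = 0.117), nor did SOX9 at -0.16 (0.481).

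Some collagen genes and 1 gene of collagen processing were lower at the anchored post as well. Of 15 fibrillar collagen genes, 3 fell and 0 rose, or 6 and 0 adjusted over the list alone (camera adjusted p = 2.15e-05, adjusted p = 0.258 with an estimated correlation). COL3A1 fell by 0.74 on the log2 scale (SE 0.165, edgeR adjusted p = 0.0185), a call that ended without anchored middle library 3 (adjusted p = 0.0702) and without anchored post library 1 (0.0951) or 3 (0.0653). COL1A1 had a log2 fold change of -0.56 (SE 0.204) and did not pass (edgeR adjusted p = 0.191). Of 19 collagen processing genes, 1 fell and 0 rose, or 9 and 0 adjusted over the list alone (camera adjusted p = 1.58e-06, adjusted p = 0.258 with an estimated correlation). That gene was LOX, which cross-links collagen and elastin, at a log2 fold change of -0.75 (SE 0.15, edgeR adjusted p = 0.00775), and its call ended without anchored post library 1 (adjusted p = 0.0616) or 3 (0.0704). XYLT1, the enzyme that starts glycosaminoglycan chains, fell by 0.53 (SE 0.1, edgeR adjusted p = 0.00428).

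Of 11 small leucine-rich proteoglycans, 1 fell and 0 rose at the anchored post, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.00505, adjusted p = 0.239 with an estimated correlation). Of 5 synovial lining genes, PRG4 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.0155, adjusted p = 0.239 with an estimated correlation and 0.127 with rank-based camera). A further 6 lists passed camera and lost that call when a single library was left out, and none passed with an estimated correlation. The tendon and fibrous tissue, TGF-beta response, glycosaminoglycan synthesis, mechanosensitive and mitochondrially encoded lists were lower by camera (estimated-correlation adjusted p = 0.258 for the first 4 and 0.433 for the last). Few of their genes passed by edgeR, all lower: ELN, INHBA, HAS2 with XYLT1, and PKD1, in the order of the first 4 lists. The mitochondrially encoded list had no such gene. The edgeR calls of ELN, INHBA and HAS2 also ended when a single library was left out. The cholesterol synthesis list was higher by camera (adjusted p = 0.553 with an estimated correlation), with no gene past the threshold by edgeR. Its call ended without anchored middle library 2 (camera adjusted p = 0.464) or anchored post library 3 (0.178). The glycosaminoglycan and mechanosensitive calls also ended with rank-based camera (adjusted p = 0.127 and 0.0966). Mitochondrial messenger RNA was 1.76% of counts at the anchored post and 2.06% in the middle, and AFP stood at 61.8 ± 18.4 and 47.3 ± 26.0 CPM (SD, n = 3). Counts in values that include split reads made up 45.5% ± 1.6 and 44.9% ± 1.93 (SD, n = 3).

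The largest falls at the anchored post otherwise lay outside the lists. They were DIPK1C by 2.26 on the log2 scale (SE 0.332, edgeR adjusted p = 0.000519), SCARA5, a ferritin receptor, by 2.02 (SE 0.279, 0.00044), HSD11B2, which inactivates glucocorticoids, by 1.73 (SE 0.223, 0.000341), NPTX1 by 1.59 (SE 0.22, 0.00044), CCN5 by 1.49 (SE 0.249, 0.0019) and HP, the gene of haptoglobin, by 1.43 (SE 0.188, 0.000341). PKD1, the gene of polycystin 1, fell by 0.75 (SE 0.123, edgeR adjusted p = 0.0016). Fewer genes rose. MT1A went from 90.5 ± 17 to 153.6 ± 22.8 CPM (SD, n = 3), a log2 fold change of 0.78 (SE 0.133, edgeR adjusted p = 0.00221). Of its counts, 69.8% sat in values that include split reads. PLAA rose by 0.62 (SE 0.113, edgeR adjusted p = 0.00359). LMNB1, BAX, FEZ1, CKS1B, TMEM158 and DESI1 rose by 0.73, 0.65, 0.56, 0.55, 0.55 and 0.55 (edgeR adjusted p at most 0.0368). Unlike the calls of MT1A and PLAA, each of these calls ended when some single library was left out.

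Together, 227 of 11834 genes differed between anchored post and anchored middle, 30 higher and 197 lower at the post (edgeR). The count was 96 without anchored middle library 3, 121 without anchored post library 1 and 62 without anchored post library 3. Without the 3 shallowest libraries, one of which is anchored middle library 2, it was 202. The share of higher genes depended on the method: 51 of 227 (22.5%) were higher with upper-quartile scaling, 68 of 266 (25.6%) with DESeq2 and 132 of 479 (27.6%) with limma voom, against 13.2% as reported.

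In unanchored tissues the post region was lower in an overlapping set of genes. FGL2, a fibrinogen-like protein, averaged 35.6 ± 6.52 CPM in unanchored middle and 15.8 ± 1.36 in unanchored post (SD, n = 3), a log2 fold change of -1.17 (SE 0.167, edgeR adjusted p = 0.00209). SFRP2, a secreted protein that binds Wnt ligands, rose from 0.705 ± 0.398 to 4.58 ± 0.0919 CPM (SD, n = 3), a log2 fold change of 2.61 (SE 0.374, edgeR adjusted p = 0.00209) at a low level. These calls held without each library in turn, unlike those of the other genes named here, all of which ended without unanchored middle library 2. HP fell by 1.14 (SE 0.177, edgeR adjusted p = 0.00386, and 0.0702 without that library), PRG4 by 1.01 (SE 0.18, edgeR adjusted p = 0.0134, 0.129 without it and 0.141 without unanchored post library 3) and PKD1 by 0.70 (SE 0.123, edgeR adjusted p = 0.0134, 0.129 without it and 0.075 without unanchored post library 1). DIPK1C, SCARA5, CCN5, CHI3L1 and HSD11B2 had log2 fold changes of -1.60, -1.43, -1.27, -1.075 and -1.04. ARPC3, MT1A, ACYP1 and UBE2B rose by 0.69, 0.62, 0.56 and 0.445 on that scale (edgeR adjusted p at most 0.0414 for these and the falls). COMP had a log2 fold change of -1.26 (SE 0.291) and just missed the threshold (edgeR adjusted p = 0.0503).

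Of 19 collagen processing genes 0 passed in unanchored tissue over all genes and 7 fell adjusted over the list alone (camera adjusted p = 2.51e-06, adjusted p = 0.344 with an estimated correlation). For 15 fibrillar collagen genes the counts were 0 and 5 (camera adjusted p = 2.08e-05, adjusted p = 0.35 with an estimated correlation), and for 12 tendon and fibrous tissue genes 0 and 4 (camera adjusted p = 0.00103, adjusted p = 0.344 with an estimated correlation). For 14 cartilage matrix genes they were 0 and 6 (camera adjusted p = 0.00103, adjusted p = 0.378 with an estimated correlation), and that call ended without unanchored post library 3 (adjusted p = 0.161). Of 9 mechanosensitive channel and cilium sensor genes, PKD1 fell and 0 rose, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.00426, adjusted p = 0.344 with an estimated correlation). The list that rose had 4 genes of the Wnt pathway, of which SFRP2 alone passed, also adjusted over the list alone (camera adjusted p = 0.012, adjusted p = 0.344 with an estimated correlation and 0.0751 with rank-based camera). A further 2 lists, TGF-beta response genes and mitochondrially encoded genes, were lower by camera (adjusted p = 0.0207 and 0.00103, adjusted p = 0.354 and 0.378 with an estimated correlation) and lost that call when a single library was left out. Other shares moved with region as well. Mitochondrial messenger RNA was 1.81% of counts at the unanchored post and 2.21% in the middle, and ribosomal RNA 0.154% ± 0.119 and 0.05% ± 0.0171 (SD, n = 3). Counts in values that include split reads made up 47.0% ± 0.322 and 43.4% ± 0.666 (SD, n = 3). AFP had 60.8 ± 19.2 and 32.8 ± 8.42 CPM and the lung gene SFTPC 7.31 ± 2.34 and 4.14 ± 0.639 CPM (SD, n = 3).

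Altogether 53 genes differed between unanchored post and unanchored middle, 8 higher and 45 lower (edgeR). The count depended on single libraries: it was 14, 3 and 129 without unanchored middle library 1, 2 or 3, and 16, 25 and 7 without unanchored post library 1, 2 or 3. Other tools gave more, 133 with DESeq2 and 511 with limma voom, of which 43.6% and 41.5% were higher, against 15.1% with edgeR.

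The region effect was shared between mold types. Of the 227 genes called in anchored tissues, 225 (99.1%) had the same sign in unanchored tissues, and the fold changes correlated at r = 0.54 across all genes. Both comparisons called 3 genes higher and 41 lower at the post, against 0 and 0.7 for independent lists, and they have no library in common. Genes past the threshold in anchored tissue and not in unanchored tissue were not shown to differ between mold types, since the interaction called 0 genes (below). Averaged over both mold types, a comparison added after the data were seen, 1007 genes differed by region, 393 higher and 614 lower at the post (edgeR), and 648, 465, 602 and 634 without unanchored middle library 1, unanchored middle library 2, unanchored post library 3 or anchored middle library 3.

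**Figure D3:**
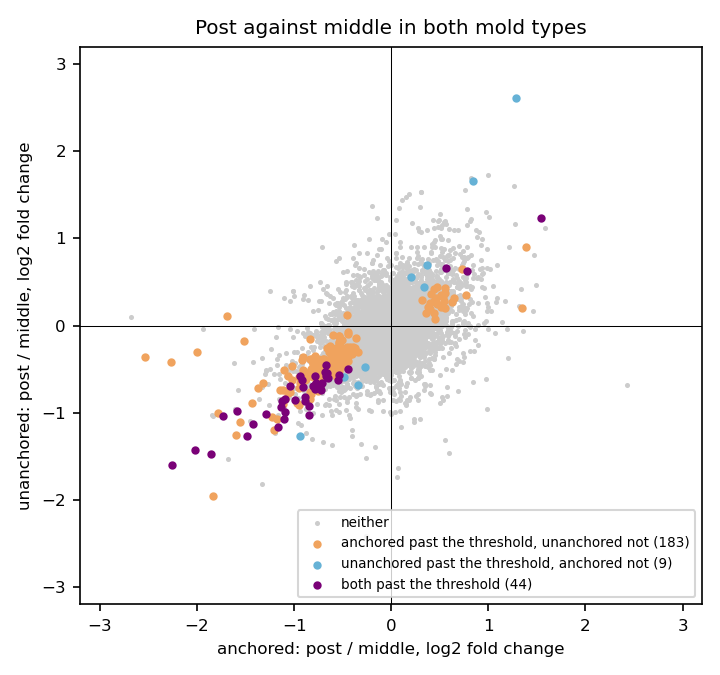
Log2 fold change of post against middle in anchored tissues (horizontal) and in unanchored tissues (vertical), 1 point per tested gene, coloured by which comparison passed an edgeR adjusted p of 0.05. Of the 227 genes called in anchored tissues, 225 have the same sign on both axes, and 44 genes passed in both.

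The comparison of anchored with unanchored tissue asked what the post anchors changed within each region. No gene passed in either region. In the middle region COL2A1 had a log2 fold change of 1.19 (SE 0.376, edgeR adjusted p = 1) and CNN1, the gene of the smooth muscle protein calponin, 0.42 (SE 0.191, edgeR adjusted p = 1). In the post region COL2A1 was at 0.46 (SE 0.392) and CNN1 at 0.57 (SE 0.182), both with an edgeR adjusted p of 1. COL2A1 in anchored middle rested on 1 library, with 276.6 CPM in library 2 against 104 and 85.5 in libraries 1 and 3. COL1A1 had log2 fold changes of 0.13 (SE 0.204) and 0.21 (SE 0.204) in middle and post, and ACTA2, the gene of smooth muscle actin, 0.28 (SE 0.138) and 0.31 (SE 0.138), with 85.9% of ACTA2 counts in values that include split reads. CCN1 and CCN2, targets of the mechanically regulated coactivator YAP, were at 0.26 and -0.02 in the middle and at 0.28 and 0.08 in the post region.

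Some lists passed camera although 0 of their genes passed over all genes tested. None of them passed fry, which asks whether the genes of a list moved on balance one way (adjusted p = 0.669 for the 4 lists in the middle and 0.953 for the 2 in the post region). The 14 contractile genes had a median log2 fold change of 0.26 in the middle (camera adjusted p = 8.94e-05, adjusted p = 0.512 with an estimated correlation) and 0.22 in the post region (camera adjusted p = 9.16e-09, adjusted p = 0.671 with an estimated correlation), with 0 genes passing adjusted over the list alone. The 20 hypoxia-responsive genes had medians of 0.33 (camera adjusted p = 1.07e-06, adjusted p = 0.512 with an estimated correlation) and 0.23 (camera adjusted p = 3.28e-04, adjusted p = 0.888 with an estimated correlation), with 5 and 0 genes higher adjusted over the list alone. The 14 cartilage matrix genes had a median of 0.35 in the middle region (camera adjusted p = 3.39e-09, adjusted p = 0.464 with an estimated correlation), with 0 genes adjusted over the list alone, and the 19 cholesterol synthesis genes a median of -0.11 (camera adjusted p = 9.25e-04, adjusted p = 0.512 with an estimated correlation). Without anchored middle library 2, which stood apart on the second principal component, the middle-region calls of the contractile, hypoxia and cholesterol lists ended (camera adjusted p = 0.261, 0.415 and 0.592) and that of the cartilage list did not (6.64e-05). The contractile and cholesterol calls also ended without unanchored middle library 3 (adjusted p = 0.113 for both), and the hypoxia call in the post region without anchored post library 2 (0.107).

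By edgeR 0 of 11834 genes passed in the middle region, with 366 at an unadjusted p under 0.05. In the post region 0 passed, with 454. Chance alone gives about 592, so both numbers fell short of it and these p-values may be conservative. The numbers were 206 and 243 with DESeq2 and 502 and 894 with limma voom. With 1 library left out at a time, edgeR gave 233 to 792 in the middle and 277 to 663 in the post region. The 0 calls therefore do not show that the anchors had no effect. DESeq2 and limma voom also called 0 in both, and edgeR without a filter on low counts called 28 and 21. In simulated data with known changes the same comparison recovered 83.6% of 2-fold changes in the middle (11703 genes) and 87.9% in the post region (11700 genes), and 54.5% and 43.3% of 1.5-fold changes. Each simulation changed 200 genes and raised a further small list 1.5 fold, and genes varied independently with no library set apart. The adjustment is stricter when fewer genes change, so recovery in the real data could be lower. Averaged over both regions, another comparison added after the data were seen, edgeR called 0 genes, with 648 at an unadjusted p under 0.05 and a smallest adjusted p of 0.817. It called 1 gene with the replicate number as a block (edgeR adjusted p = 0.025) and 1 without anchored middle library 3 (0.0343).

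**Figure D4:**
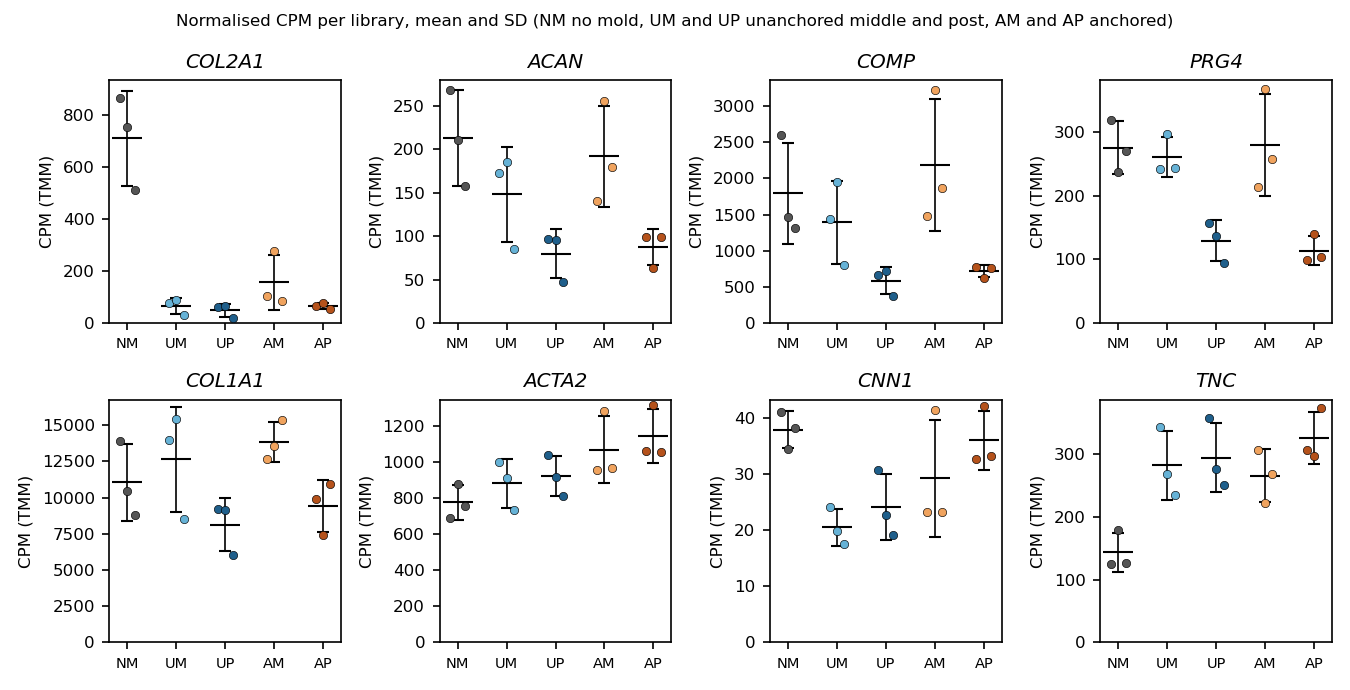
TMM-normalised CPM of 8 genes in each library (points), with the mean and SD of the 3 libraries per group, each vertical axis starting at 0. COL2A1 is 708 CPM without a mold and at most 155.5 in a molded group, COMP and PRG4 are lower at the post than in the middle of both mold types, and the anchored and unanchored groups of one region overlap for COL1A1.

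The interaction asked whether the effect of the anchors differed between the post and the middle region. It called 0 genes by edgeR, with 223 at an unadjusted p under 0.05. That number also fell short of the about 592 that chance alone gives, so these p-values may be conservative too. DESeq2 and limma voom called 0 as well, with 92 and 567 under 0.05 unadjusted, while edgeR without a filter on low counts called 3. COL2A1 had an interaction of -0.73 (SE 0.541) and COMP of -0.34 (SE 0.406) on the log2 scale, both with an edgeR adjusted p of 1. The log2 fold changes of anchoring in the 2 regions correlated at r = 0.18 across genes. The cartilage matrix list was the 1 list of 29 that passed, lower in the post relative to the middle (median -0.29, camera adjusted p = 0.00575, adjusted p = 0.962 with an estimated correlation, 0 of 14 genes, also adjusted over the list alone). The call ended without unanchored middle library 3 (camera adjusted p = 0.624), unanchored post library 1 (0.119) or 2 (0.256), anchored middle library 2 (0.241) or anchored post library 2 (0.0554). In simulated data, also with 200 genes changed and a further small list raised, the interaction recovered 66.7% of 2-fold and 16.7% of 1.5-fold changes (11716 genes). With fewer changed genes recovery could be lower.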

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

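For these results, the tests chosen only after the result was seen were equal depth and the no-mold library slope for the mold effect, the library slope for the region effect, and the estimated correlation for the cartilage list. A first test of depth, a slope of fold changes on thinned counts, was dropped because thinning preserves fold changes by construction.

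The effect of the anchors on cartilage matrix genes differed between regions by camera (adjusted p = 0.00575 for the interaction, median log2 -0.29), with a higher list in anchored than in unanchored middle (median 0.35, camera adjusted p = 3.39e-09, but 0.464 with an estimated correlation). Without anchored middle library 2 the interaction's adjusted p was 0.241 and its median -0.07, and the median in the middle region was 0.20 (camera adjusted p = 6.64e-05). The interaction call also ended without unanchored middle library 3 (0.624), unanchored post library 1 (0.119) or 2 (0.256) or anchored post library 2 (0.0554), so whether anchored middle library 2 alone made the pattern is undecided. With the correlation among the list's genes estimated, the interaction had an adjusted p of 0.962, in line with genes of one list moving together between libraries. A biological difference between the regions stays open as untested, and 90 of 100 splits of the molded libraries gave at least as many lists as the 1 seen, with a highest of 15, so chance is not excluded.

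Many genes differed between molded and no-mold libraries (1888). With every library thinned to the smallest total, 1416 of these, 75.0%, were kept with the same sign. Unequal depth in the counts was therefore not needed for most of the calls. Because thinning preserves fold changes, it cannot test whether other changes went with low depth in the no-mold libraries, and that stays open. Whether no-mold libraries 1 and 3 alone made the pattern is undecided: over 1504 genes called from them, no-mold library 2 against the same molded libraries gave a slope of 0.49 (95% bootstrap interval 0.428 to 0.55) with 93.9% of genes of the same sign, against a limit of 0.5 for excluding it, and the molded libraries are common to both sides, which raises the slope. Of 100 splits of the libraries the real one gave the most genes, with 139 as the highest of the others. Such a count is unlikely from a random assignment of these libraries. The other splits mix groups that differ, which can widen the fitted spread and lower their counts. Chance between tissues is not excluded, since the labels do not say whether replicates came from separate tissues. An effect of the mold itself and any difference in handling that follows the groups cannot be told apart from these labels, and neither was tested.

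Genes differed between the post and the middle in both mold types, more of them lower than higher at the post. Over the 227 genes called in anchored tissues, the unanchored fold changes, which use none of the same libraries, had a slope of 0.64 on the anchored ones (95% bootstrap interval 0.574 to 0.697), which argues against anchored middle library 2 alone as the cause. Among genes with only whole values 7.00% were called in the mean over mold types, against 10.3% of the other genes, a ratio of 0.68 (0.606 to 0.761), which argues against reads split between similar genes as the whole cause. Of 100 splits the real one gave the most genes (1007, highest other 84). That count is unlikely from a random assignment of these libraries, but chance between tissues is not excluded, for the reason given above. The 1007 genes and the shares of genes called hold both directions, 393 higher and 614 lower at the post. They therefore bear on a region difference and not on its direction. In this mean comparison 45.9% of the calls were higher with DESeq2 and 45.0% with limma voom, against 39.0% with edgeR. A difference between the regions remains open as untested, as does any difference in dissection or position that follows them.

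For the other counts, 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real split gave 227 genes for anchored post against middle (1 split as large, highest other 0), 53 for unanchored post against middle (1, 0), and 1575, 658, 1747 and 1068 for anchored middle, anchored post, unanchored middle and unanchored post against no mold (1 each, highest others 28, 1, 0 and 0). It gave 0 for anchored against unanchored in both regions, as did all 10 splits. For the interaction (0 genes) and the mean effect of the anchors (0 genes), all 100 splits gave as many, the highest 184 and 340. These splits point to the region effect as a structure of the samples: the highest came when 5 of 6 libraries on a side were of one region (4 and 9 splits), while the 42 and 47 splits with 3 of 6 gave 0, a comparison made after the counts were seen. For lists, 7 of 10 splits gave as many as the 4 in anchored against unanchored middle (highest other 7), 9 of 10 as many as the 2 in the post region (11), 1 of 10 as many as the 11 for anchored post against middle (10), 3 of 10 as many as the 8 for unanchored post against middle (10), and 11 of 100 as many as the 8 for molded against no mold (14), so chance is not excluded for the last.

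Counts were present in ERCC spike-in rows, which no comparison used and whose use the labels do not mention: 28 of 92 sequences had a count, with 18 to 70 counts per library and the most in anchored post library 3.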

How the results depend on the processing

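No call of a named gene reversed its sign in any setting tried, and of 83 calls of named genes 38 held in every setting in which each was tested except the test against a 2-fold change. Thinning, whole values and the removal of shallow libraries were chosen after seeing the data, as were the 2 mean comparisons. Total counts of calls under RLE and upper-quartile scaling and the stricter filter stayed within 1.5 times those reported, but the higher genes at the anchored post went from 30 to 51 with upper-quartile scaling. In data simulated at the real depths 16.7% of 1.5-fold interactions were found.

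Without a filter, edgeR called 28 and 21 genes for anchored against unanchored in middle and post, 66 for their mean, 479 for anchored and 272 for unanchored post against middle (185 common), and 3 for the interaction. The cause was not tested. DESeq2 called 133 for unanchored post against middle (68 common), and limma voom 479 and 511 for the region comparisons (205 common) and 1706 for their mean, and the cause was not tested. With only the groups compared in the model, the region comparisons had 105 (anchored) and 192 (unanchored). This setting does not exist for the mean of the molded groups, which uses every library. Against a 2-fold change, a stricter question, 0 genes passed for either region comparison, for their mean and in common, 5 for molded against no mold, and 2, 5, 8 and 6 for anchored middle, anchored post, unanchored middle and unanchored post against no mold.

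At equal depth 557 genes passed for the mean region effect and 28 in common, with fewer reads and 10071 genes tested. With only whole values, where fewer genes are tested, the counts were 105, 35 and 396 for anchored, unanchored and mean region effects (25 common), 788 for molded against no mold, and 661, 270, 692 and 467 for the 4 groups in the above order. Without the 3 shallowest libraries, they were 148 for unanchored post against middle, from which no library was left out (cause not tested), 85 in common, 335 for molded against no mold and 411, 82, 421 and 170 for the 4 groups, with 1 list for anchored against unanchored middle and 2 for the interaction. With rank-based camera 5 of 34 list calls ended. With an estimated correlation 0 lists passed in each of the 6 list comparisons.

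Whether replicate numbers pair the samples stays open, since the labels do not say and the values do not settle it. Deviations from the group mean of same-numbered middle and post libraries correlated at -0.03 to 0.14 in anchored and 0.09 to 0.26 in unanchored tissue. They were over the limit of 0.1 in 1 and 2 of 3 pairs. Among the libraries of other groups, 10 of 15 libraries correlated best with one of their own number, where chance would give about 1 in 3. That count leans towards pairing, but the best matches of different libraries depend on one another. The reported tests treat the libraries as unpaired. With the replicate block 1 gene passed for the mean effect of the anchors. The block moved no other count by over 1.5 times.

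Leaving out 1 library at a time gave 62 to 283 genes for anchored and 3 to 129 for unanchored post against middle, 465 to 1150 for their mean, 856 to 2297 for molded against no mold, and 768 to 1861, 251 to 616, 790 to 1491 and 496 to 1076 for the 4 groups. It gave 0 to 0 for both anchoring comparisons and the interaction, and 0 to 1 for the mean effect of the anchors (1 without anchored middle library 3). Lists numbered 1 to 8 and 1 to 4 for the anchors in middle and post, 8 to 12 and 6 to 8 for region in anchored and unanchored tissue, 0 to 4 for the interaction and 7 to 9 for molded against no mold.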

Other observations

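The genes in these paragraphs were chosen after their values were seen, and the region values use the mean over both mold types, a comparison added after the data were examined. Of the complement genes, C1R fell at the post by 0.88 on the log2 scale (SE 0.14, edgeR adjusted p = 0.000359), C1S by 0.54 (SE 0.093, edgeR adjusted p = 0.000885) and SERPING1, the C1 inhibitor, by 1.04 (SE 0.162, edgeR adjusted p = 0.000277), while C3 had a log2 fold change of -0.14 and did not pass (edgeR adjusted p = 0.64). IGFBP3, which binds insulin-like growth factors, was lower at the post, with 1328 and 1204 CPM in unanchored and anchored middle against 695 and 548 at the posts, a log2 fold change of -1.04 (SE 0.101, edgeR adjusted p = 2.87e-06). The chemokine CXCL12 fell by 0.60 (SE 0.081, edgeR adjusted p = 5.27e-05). Higher at the post were the ferritin chains FTH1 (0.44, SE 0.081, edgeR adjusted p = 0.00164) and FTL (0.44, SE 0.076, edgeR adjusted p = 0.000935), the redox enzymes TXN (0.44, edgeR adjusted p = 0.00281) and TXNRD1 (0.39, edgeR adjusted p = 0.00122), and MSLN, a surface protein of mesothelial cells, by 1.39 (SE 0.183, edgeR adjusted p = 4.39e-05) from 2.16 and 2.42 CPM in unanchored and anchored middle.

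Between molded and no-mold tissue, PTN, the heparin-binding factor pleiotrophin, rose from 49.9 CPM to between 124 and 150 CPM in the molded groups, a log2 fold change of 1.52 (SE 0.116, edgeR adjusted p = 1.59e-08). The proteoglycans ASPN and DCN rose by 1.34 (SE 0.134, edgeR adjusted p = 5.86e-07) and 0.85 (SE 0.088, edgeR adjusted p = 8.34e-07), and the basement membrane genes COL4A1 and NID1 by 1.28 (SE 0.247, edgeR adjusted p = 0.00102) and 1.00 (SE 0.147, edgeR adjusted p = 6.62e-05). HMOX1 (heme oxygenase) fell by 0.84 (SE 0.108, edgeR adjusted p = 1.33e-05).

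Some transcripts known from liver and lung were present in every library, from a list written after values were seen. AFP had 160 to 568 counts per library, ALB 50.0 to 173 and SFTPC, a lung surfactant gene, 22.0 to 70.0, while the abundant liver transcripts AHSG and SERPINA1 had 3 and 1 counts over all libraries. Of 4 relations computed across the 15 libraries on log2 CPM, AFP correlated with SFTPC at r = 0.97 and rho = 0.96 (permutation p = 1e-05 for both, the smallest the permutations can give, adjusted 2e-05 and 4e-05), with ALB at r = 0.95 and rho = 0.90 (permutation p = 1e-05 and 4e-05, adjusted 2e-05 and 8e-05), and with the spike-in share at r = 0.86 and rho = 0.80 (permutation p = 7e-05 and 0.00072, adjusted 9.33e-05 and 0.00096). AFP fell with library total, r = -0.76 and rho = -0.69 (permutation p = 0.00064 and 0.00556, adjusted 0.00064 and 0.00556). Without the 2 libraries farthest from the median, no-mold 1 and 3, these r were 0.97, 0.92, 0.87 and -0.51, and over the 12 molded libraries 0.98, 0.92, 0.89 and -0.55. Every share here is divided by the library total. That division alone can give positive relations between shares and a negative relation with the total. The permutations do not allow for it, so their p-values do not show a relation beyond it. If division alone made the relations, AFP would correlate with another share no more strongly than with the total, apart from sampling spread. Over the 12 molded libraries the r were 0.98, 0.92 and 0.89 with the other shares and -0.55 with the total. These values argue against division alone in these libraries, though no interval was computed for the gap. What links these transcripts was not tested.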
